A study of Homo sapiens with 10 samples.

How the data were processed

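RNA levels were measured with Affymetrix exon arrays in 10 samples of SH-SY5Y, a human neuroblastoma cell line with noradrenergic properties. The cells were stably transfected with wild-type SOD1 or with SOD1(G93A), a mutant form found in familial amyotrophic lateral sclerosis (ALS). There were 5 arrays per group. Per the labels' protocols, cells were grown with G418 to keep the transfected DNA, RNA was extracted with TRIzol and cleaned on silica columns, and ribosomal RNA was depleted before labelling.

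The deposited values are gene-level log2 intensities, 1 per probe set and array, for 22011 probe sets. Per the submitters' processing notes the authors used RMA, and per the labels they worked in oneChannelGUI 1.6.5. RMA subtracts background, makes the distributions of the arrays alike by quantile normalization and summarises probes on a log2 scale, so a shift of all genes together would not be visible. Differences of dim probes are compressed, and the table carries no detection calls. The size of a large fold to or from a level below the lower quartile of the probe sets is therefore uncertain, and the printed value may understate it. That quartile lay between 3.84 and 3.89 on the log2 scale in the 10 arrays. The genome build and the filters behind the table are not given in the sources used here. The number of arrays limits the precision.

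Probe sets were named through the platform annotation. Of the 22011 probe sets, 14432 had exactly 1 gene symbol, 2408 had several and 5171 had none. No gene was named from a probe set with several symbols. Symbols were checked through gene identifiers against the RefSeq gene table of assembly GCF_000001405.40 GRCh38.p14, in which 28 single-symbol probe sets had no match. For each of the 14232 named genes, the probe set with the highest mean over all 10 arrays was used. That table also gave the order of neighbouring genes; none of its positions is printed.

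Groups were taken from the sample labels, and samples are called by the sample number in their titles. The wild-type SOD1 samples were 2, 8, 11, 14 and 17, and the SOD1(G93A) samples were 3, 9, 12, 15 and 18. Whether the 5 samples of a group came from separate cultures is not given in the sources used here, nor whether each line was a clone or a pool. The p-values therefore measure only the spread between these samples, which may be technical, and the construct cannot be separated from any other difference between the transfected lines.

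The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, 2-sided), with Benjamini-Hochberg adjustment over all 22011 probe sets and no filter on level. A probe set was called at an adjusted p of 0.05 or less, the false discovery rate the labels state. A second count also asked for an absolute log2 fold change of at least 1, as the labels do. All fold changes are SOD1(G93A) minus wild-type SOD1, with the moderated standard error (SE). SOD1 and the means of gene lists were also tested by an exact permutation test of the 10 values, 2-sided, whose smallest possible p is 0.00794. For the lists this p is printed without adjustment unless an adjusted p is given.

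A total of 26 gene lists was fixed before the data were examined: antioxidant enzymes, NRF2 targets, glutathione and metallothioneins, unfolded protein response, cytosolic chaperones, proteasome, autophagy and lysosome, respiratory chain, glycolysis and hypoxia, neuronal cytoskeleton, axon guidance, synaptic vesicle release, glutamate receptors and calcium, noradrenergic identity, cholinergic genes, mesenchymal (S-type) markers, Schwann and glial markers, immune and endothelial markers, collagens and matrix, DNA replication, mitosis, p53 targets and apoptosis, interferon and NF-kB response, cholesterol synthesis, splicing factors, and ALS genes. They held 837 different genes, of which 684 were measured. Lists were tested with camera at a preset correlation of 0.01, with adjustment over the 26 lists, and again with an estimated correlation and with fry. A 1-sided Fisher's exact test of the number of called members was added after the data were seen. Median, mean and camera direction differed in sign for the glutathione, neuronal cytoskeleton, axon guidance, noradrenergic and matrix lists, none of which camera called. A further 6 lists (potassium, sodium and HCN channels, imprinted genes, retinoic acid targets, cancer-testis genes, HOX genes and abundant S-type or stromal transcripts) were written after the largest changes had been seen, and their results stand in the closing part. The genes that prompted a list were left out of its test for 5 of these lists and not for the stromal transcripts. Counts of called members are given over all probe sets and, where stated, adjusted over the list alone.

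The genes named were set by a rule fixed before the data were examined. It took SOD1, then the 12 largest rises and the 12 largest falls among named genes past the threshold with no overlap between the groups, and then up to 4 called members of each list by size of change. For a list with no called member it took the member with the largest change, given as a value. Further members of some lists were named after their values were seen, and this is said where it applies. For genes of closely similar families (TUBB4A, AKR1C3, FTL), cross-hybridisation cannot be excluded.

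The alternatives were quantile normalization, median centring, array weights, adjacent sample numbers as a block, leaving out each array, only probe sets brighter than the median one, a trended and robust prior, an unmoderated test, 1 probe set per gene and the mean of a gene's probe sets. Residuals of arrays with adjacent sample numbers correlated at −0.03 to 0.14, and the labels do not call them pairs. No 2 arrays were duplicates: the differences between arrays of a group had a standard deviation of 0.28 to 0.36. Added after the data were seen were the omission of samples 17 and 18 together and the omission of a run of neighbouring genes. Runs were sought with a running median of 21 named genes against 1000 shuffled gene orders. Other groupings were drawn as 100 of the 126 possible splits into 5 and 5.

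The fit was tested on simulated data for this comparison, with 22011 probe sets of which 66 were changed by 0.50 log2 and 67 each by 1 and 2. It recovered 60.6%, 89.6% and 100% of them, and 8 of 175 calls were false. Noise was drawn independently for each probe set. Real genes can move together between arrays, so these rates need not hold for the real data. Figures were drawn with matplotlib 3.10.9.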

Results

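The series compared SH-SY5Y cells carrying wild-type SOD1 with cells carrying SOD1(G93A), 5 arrays each, and asks which genes differ between the 2 lines. SOD1 encodes copper-zinc superoxide dismutase, and the G93A form causes familial ALS. Array medians lay between 6.26 and 6.34 on the log2 scale. Correlations between arrays were 0.990 to 0.994 within groups and 0.986 to 0.990 between them. The first principal component held 29.1% of the variance and separated all arrays by group. The next 2 components held 12.1% and 11.4%, and on them wild-type sample 17 and SOD1(G93A) sample 18 lay farthest from their groups.

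SOD1 was high in both lines. Its level was 9.78 ± 0.13 (SD, n = 5) with the wild-type construct and 9.55 ± 0.09 (SD, n = 5) with SOD1(G93A), above 91.9% of the probe sets. The SOD1(G93A) level was 85.4% of the wild-type level (log2 fold change −0.23, 95% interval −0.39 to −0.06). By limma the difference was not past the threshold over all probe sets (adjusted p = 0.107), and the exact permutation test of this single gene gave p = 0.0159. The probe set may read endogenous and transfected SOD1 together, and which of its probes match the construct was not examined. Its gene-level value does not tell the mutant from the wild-type sequence, and so does not check the labels.

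Among the largest rises in the SOD1(G93A) line was HGF, the ligand of the MET receptor, from 2.75 ± 0.20 to 8.44 ± 0.32 (SD, n = 5 each; log2 fold change 5.70, SE 0.15). S100A10, the annexin A2 partner, rose by 4.25 (SE 0.25), and BCHE, the butyrylcholinesterase gene, by 3.51 (SE 0.16). MAGEA10, a cancer-testis antigen, rose by 3.40 (SE 0.09), and MAB21L2, a gene of eye development, by 3.24 (SE 0.10). Smaller rises were those of MOXD1 (2.78), the receptor phosphatase PTPRR (2.67), the fibrillar collagen COL3A1 (2.33), the peroxidase GPX8 (2.33), the orphan receptor GPR22 (2.31), the retinoic acid carrier CRABP2 (2.25) and the secreted protein gene CCDC80 (2.16). HGF, BCHE, MOXD1, GPX8 and CCDC80 started below the lower quartile of the probe sets, where log2 differences are compressed.

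The largest fall among named genes was that of NNAT, an imprinted gene of the nervous system, from 11.14 ± 0.14 to 5.19 ± 0.11 (SD, n = 5 each; log2 fold change −5.95, SE 0.08), or 61.7-fold. The chemokine receptor CXCR4 fell by 3.97 (SE 0.13), the relaxin receptor RXFP1 by 3.82 (SE 0.08), the transcriptional regulator LMO3 by 3.60 (SE 0.11) and the prion protein gene PRNP by 2.76 (SE 0.17). The glutamate receptor GRM8 fell by 2.73 and the phosphatase subunit PPP2R2C by 2.50. TUBB4A, a neuronal tubulin with close relatives, fell by 2.34, and the kinase PRKCA by 2.30. The homeobox gene HOXC10 fell by 2.30, the zinc finger gene ZNF521 by 2.26 and the integrin ligand EDIL3 by 2.25. CXCR4, RXFP1, GRM8, HOXC10 and ZNF521 ended below the lower quartile of the probe sets, where log2 differences are compressed. In all 24 of these genes the groups did not overlap, and adjusted p values by limma ran from 2.21e-11 for NNAT to 2.88e-05 for HOXC10.

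**Figure D1:**
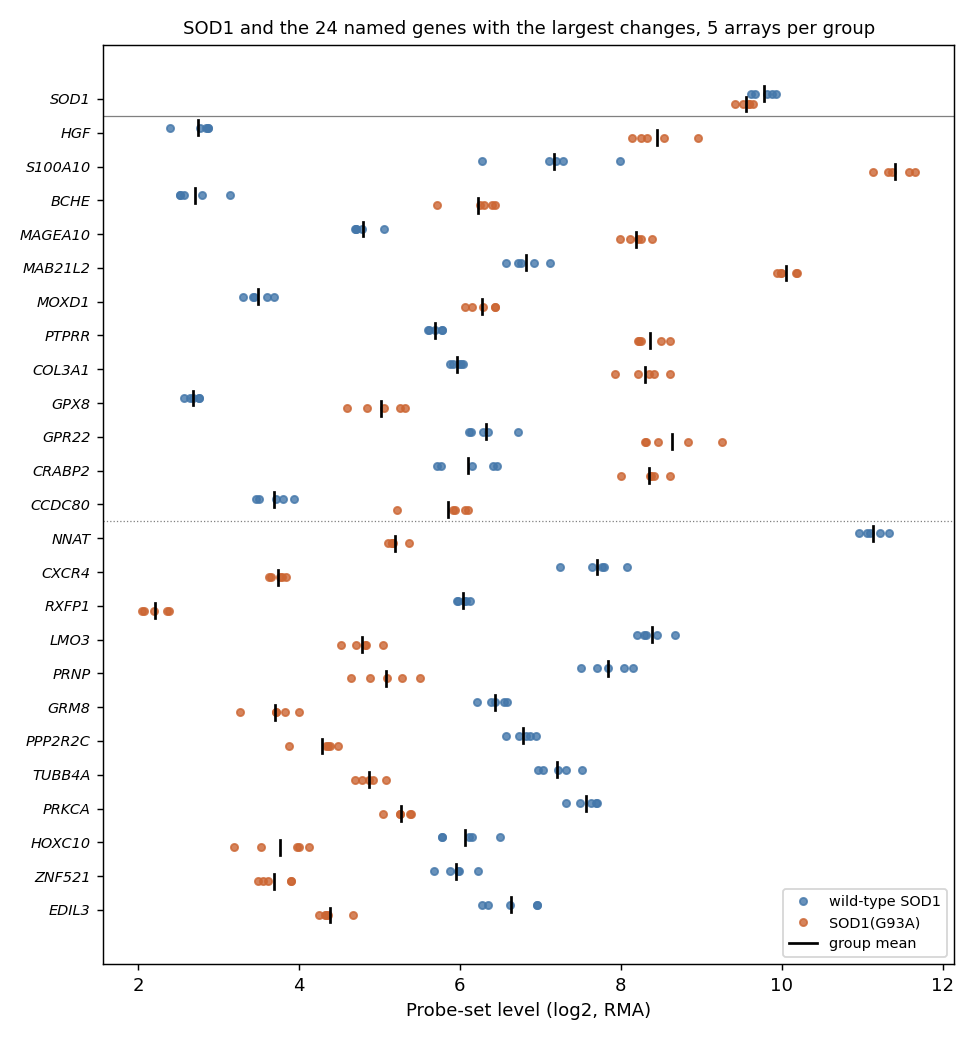
Levels of SOD1 and of the 24 named genes with the largest changes (log2, horizontal axis), with 1 point per array, 5 per group, and a bar at each group mean. The groups of SOD1 overlap, while those of the other genes, HGF to EDIL3, do not.

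Over the whole array, 1643 of 22011 probe sets were past an adjusted p of 0.05 by limma, 713 higher and 930 lower in the SOD1(G93A) line. With the labels' 2-fold threshold added, 192 remained, 81 higher and 111 lower. Among the 14232 named genes, 1366 were called, 573 higher and 793 lower, or 9.60%, and the groups did not overlap in 1257 of them. Over all probe sets 8.88% had no overlap, against 0.794% by chance. Among probe sets brighter than the median one, tested alone, the count past both thresholds was 92.

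Genes of axon guidance changed in both directions. Of 42 measured, 10 rose and 11 fell (11 and 13 adjusted over the list alone). The repulsive cue SEMA3A rose by 1.71 (SE 0.11), NRP2, a coreceptor of class 3 semaphorins, by 1.57 (SE 0.11) and the adhesion molecule NCAM2 by 1.63 (SE 0.06), while the adhesion molecule NRCAM fell by 1.40 (SE 0.08). Named after their values were seen, SEMA3D rose by 1.14, and CNTN4 and SLIT1 fell by 1.02 and 0.94. By camera the list did not move one way (adjusted p = 0.925). Its 21 called genes were more than the 9.60% of all named genes would give (Fisher's exact test, added after the data were seen, adjusted p = 7.06e-10).

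Genes of synaptic vesicle release were more often higher. Of 27 measured, 7 rose and 3 fell (13 and 3 adjusted over the list alone). The granule proteins CHGB, CHGA and SCG2 rose by 1.40 (SE 0.15), 1.06 (SE 0.12) and 0.90 (SE 0.10), and the active-zone gene RIMS1 fell by 1.30 (SE 0.07). PCLO, SYT1 and SNAP25, named after their values were seen, rose by 0.74, 0.69 and 0.44. The list's mean level was 7.27 ± 0.05 in wild-type and 7.47 ± 0.05 in SOD1(G93A) arrays (SD, n = 5; exact permutation p = 0.00794, the smallest possible). Camera called the list higher (adjusted p = 0.00308), but not with an estimated correlation (adjusted p = 0.467).

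Among 26 genes of the neuronal cytoskeleton, 6 rose and 3 fell (7 and 7 adjusted over the list alone). STMN4, a stathmin, rose by 1.33 (SE 0.13) and PRPH, the intermediate filament peripherin, by 1.03 (SE 0.08). MAP2, a dendritic microtubule protein, fell by 0.67 (SE 0.10) and DPYSL5 by 0.53 (SE 0.08). The neurofilament light chain NEFL, named after its value was seen, fell by 0.39. Camera did not call the list (adjusted p = 0.989), while 34.6% of its genes were called (Fisher's exact test, adjusted p = 0.00201). That test ignores the correlation of the list's genes, estimated at 0.36. DPYSL5 also lay in a stretch of lower neighbouring genes, SH3YL1 to ACYP2.

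Of 33 glutamate receptor and calcium genes, 4 rose and 9 fell, with the same counts adjusted over the list alone. GRM8 showed the largest fall (2.73, above), CALB1, which encodes the calcium buffer calbindin, fell by 1.59 (SE 0.11) and the receptor GRM7 by 0.82 (SE 0.08), while the calcium channel subunit CACNA2D1 rose by 0.75 (SE 0.13). The AMPA receptor subunit GRIA2, named after its value was seen, rose by 0.73. The list mean was 5.09 ± 0.02 in wild-type and 4.93 ± 0.03 in SOD1(G93A) arrays (SD, n = 5, exact permutation p = 0.00794). Of its genes 39.4% were called (Fisher's exact test, adjusted p = 4.39e-05). Camera gave an adjusted p of 0.212. The self-contained test fry, which does not compare the list with other genes, called it lower (adjusted p = 0.000397).

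Genes of transmitter identity changed in both directions. Of 24 noradrenergic neuroblastoma genes, 4 rose and 6 fell (4 and 7 adjusted over the list alone). The neuropeptide NPY fell by 1.66 (SE 0.10) and the transcription factor GATA2 by 0.58 (SE 0.08), whereas MAOA, a monoamine oxidase, rose by 0.95 (SE 0.10) and the vesicular monoamine transporter SLC18A2 by 0.64 (SE 0.08). Of 17 cholinergic genes 2 rose and 1 fell, also adjusted over the list alone. BCHE rose (3.51, above), the acetylcholine transporter SLC18A3 fell by 1.09 (SE 0.12), and the nicotinic receptor subunit CHRNA3 rose by 0.25 (SE 0.06). The CHRNA3 call was lost without wild-type sample 2, SOD1(G93A) sample 9 or SOD1(G93A) sample 15 (adjusted p up to 0.0576). Neither list was called by camera (adjusted p = 0.925 and 0.334), and fry called the cholinergic genes higher (adjusted p = 0.032). Of the noradrenergic genes 41.7% were called (Fisher's exact test, adjusted p = 0.000232). The members SOX11 and ALK, both called lower and named for their place in the gene order, lay in the stretch from SH3YL1 to ACYP2. Fisher's exact test was not repeated without them.

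Collagens and matrix genes split. Of 46 measured, 9 rose and 8 fell (10 and 10 adjusted over the list alone). COL3A1 rose (2.33, above), while the basement membrane collagens COL4A1 and COL4A2 fell by 2.13 (SE 0.07) and 2.04 (SE 0.07) and the integrin ITGA9 by 1.71 (SE 0.10). Named after their values were seen, TIMP1, DCN and VCAN rose by 1.46, 1.34 and 1.18, and TNC fell by 1.53. Camera gave an adjusted p of 0.925, and the share of called genes was 37.0% (Fisher's exact test, adjusted p = 6.87e-06).

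Markers of the mesenchymal, substrate-adherent (S-type) state of neuroblastoma were mostly higher. Of 32 measured, 6 rose and 1 fell (9 and 3 adjusted over the list alone). YAP1 rose by 0.66 (SE 0.07), CNN2 by 0.60 (SE 0.10) and CCN1 by 0.47 (SE 0.10), and SNAI2, a mesenchymal transcription factor, fell by 1.03 (SE 0.10). The list mean was 6.02 ± 0.04 against 6.12 ± 0.04 (SD, n = 5; exact permutation p = 0.00794). Camera called it higher (adjusted p = 0.0193), but not with an estimated correlation (adjusted p = 0.467) or among the probe sets brighter than the median one (adjusted p = 0.128). Of 14 Schwann and glial markers 1, S100B, rose by 0.73 (SE 0.11) from below the lower quartile of the probe sets. None of 17 immune and endothelial markers was called by limma or the unmoderated test, with 0 at an unadjusted p under 0.05; the largest difference was 0.25 (SE 0.13) in MS4A1, which was 0.16 without samples 17 and 18 together, an omission added after the data were seen.

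Mitosis genes were lower. Of 31 measured, 8 fell and 0 rose by limma (15 and 0 adjusted over the list alone); at an unadjusted p under 0.05, 21 were lower and 0 higher. CENPA, a centromeric histone, fell by 0.77 (SE 0.06) and lay in a stretch of lower neighbouring genes, SH3YL1 to ACYP2. CDC20, an activator of the anaphase-promoting complex, fell by 0.57 (SE 0.15), the proliferation marker MKI67 by 0.47 (SE 0.10) and the kinetochore gene CENPF by 0.46 (SE 0.11). The list mean was 9.02 ± 0.06 in wild-type and 8.76 ± 0.14 in SOD1(G93A) arrays (SD, n = 5; exact permutation p = 0.00794, the smallest possible). Camera called it lower (adjusted p = 1.31e-08), but not with an estimated correlation (adjusted p = 0.467). The CDC20 groups overlapped and its call was lost without any 1 of 8 arrays (adjusted p up to 0.102); that of CENPF was lost without wild-type sample 2 or 14 or SOD1(G93A) sample 3 or 9 (adjusted p up to 0.0662).

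Of 29 DNA replication genes, 1 rose and 3 fell (1 and 7 adjusted over the list alone). The ribonucleotide reductase subunit RRM2, also in that stretch, fell by 0.43 (SE 0.07), E2F2 by 0.37 (SE 0.06) and the helicase subunit MCM2 by 0.26 (SE 0.07), and the cyclin CCNE1 rose by 0.27 (SE 0.07). The list was not called by camera at the preset correlation (adjusted p = 0.0771) or with an estimated one (adjusted p = 0.977). The omissions that follow were tested at the preset correlation only. It was called lower without wild-type sample 8 (adjusted p = 0.0438), SOD1(G93A) sample 15 (adjusted p = 0.0397) or SOD1(G93A) sample 18 (adjusted p = 0.0137), and without samples 17 and 18 together, an omission added after the data were seen (adjusted p = 0.0187). The calls of MCM2 and CCNE1 were lost without any 1 of 8 and of 7 arrays, with adjusted p up to 0.0967 and 0.0765.

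**Figure D2:**
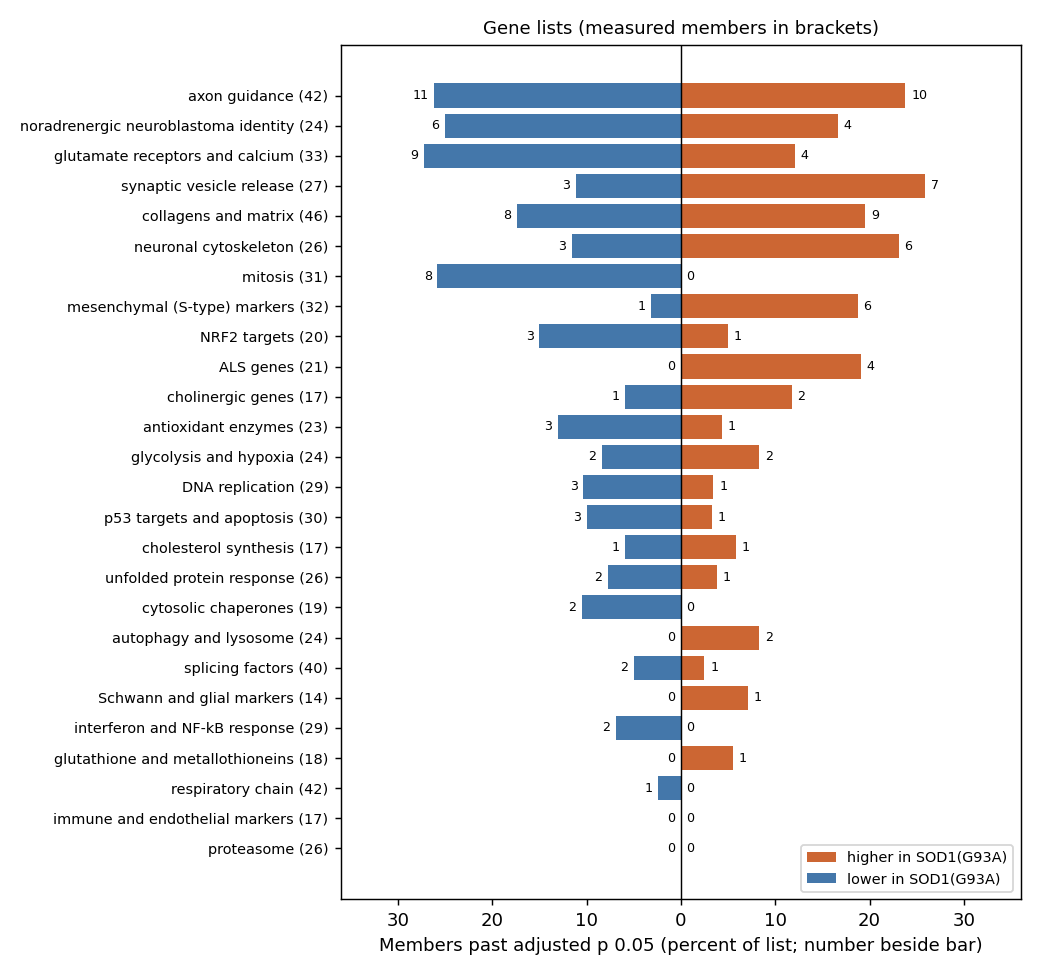
Share of each gene list's measured members past an adjusted p of 0.05 (percent, horizontal axis), to the right for genes higher and to the left for genes lower in SOD1(G93A) arrays, with the number beside each bar. Axon guidance has 10 higher and 11 lower of 42, mitosis 0 higher and 8 lower of 31, and the proteasome 0 of 26.

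Genes of oxidative defence, the field in which SOD1 acts, changed in both directions. Of 23 antioxidant enzymes, 1 rose and 3 fell (2 and 6 adjusted over the list alone). GPX8, a peroxidase of the endoplasmic reticulum, rose (2.33, above), the methionine sulfoxide reductases MSRB2 and MSRA fell by 0.83 (SE 0.10) and 0.33 (SE 0.09), and the glutaredoxin GLRX fell by 0.80 (SE 0.14). Of 20 NRF2 targets, 1 rose and 3 fell (1 and 4 adjusted over the list alone): MGST1 fell by 1.34 (SE 0.13), AKR1C3 by 0.95 (SE 0.12) and the transporter ABCC1 by 0.31 (SE 0.06), and the ferritin gene FTL rose by 0.42 (SE 0.11). Of 18 glutathione and metallothionein genes 1, the copper transporter ATP7A, rose by 1.34 (SE 0.15); adjusted over the list alone 3 rose and 1 fell. MGST1 and AKR1C3 ended below the lower quartile of the probe sets. AKR1C3 and FTL have near-identical relatives. Camera called none of the 3 lists (adjusted p = 0.307, 0.307 and 0.925). The MSRA and FTL calls were lost without any 1 of 8 and of 9 arrays (adjusted p up to 0.110 and 0.105).

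Of 26 unfolded protein response genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone): DDIT4 rose by 0.55 (SE 0.14), PDIA6 fell by 0.46 (SE 0.12) and ASNS by 0.27 (SE 0.07). Of 19 cytosolic chaperones 2 fell, HSPA2 by 0.62 (SE 0.09) and BAG3 by 0.43 (SE 0.10), also adjusted over the list alone. None of 26 proteasome genes was called by limma, 1 had an unadjusted p under 0.05, and the unmoderated test called 1; the largest difference was −0.22 (SE 0.18) in PSMC3, which was −0.04 without wild-type sample 2. Of 24 autophagy and lysosome genes 2 rose, ATG13 by 0.26 (SE 0.06) and ULK2 by 0.24 (SE 0.06), also adjusted over the list alone. None of these 4 lists was called by camera (adjusted p = 0.925, 0.307, 0.565 and 0.249). The calls of PDIA6, DDIT4, ASNS, ATG13 and ULK2 were lost without any 1 of 6 to 9 arrays (highest adjusted p 0.108, in PDIA6) and that of BAG3 without SOD1(G93A) sample 9 (adjusted p = 0.0569).

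In energy metabolism, 1 of 42 respiratory chain genes fell, the complex III subunit UQCRQ by 0.37 (SE 0.09), and 0 did so adjusted over the list alone. Of 24 glycolysis and hypoxia genes 2 rose and 2 fell (3 and 2 adjusted over the list alone). The hexokinase HK2 rose by 0.58 (SE 0.09) and the aldolase ALDOC by 0.41 (SE 0.09), and the phosphofructokinase PFKP fell by 0.49 (SE 0.09) and the peptide hormone gene ADM by 0.49 (SE 0.07). Of 17 cholesterol synthesis genes, the sterol carrier STARD4 rose by 0.87 (SE 0.09) and the mevalonate kinase MVK fell by 0.45 (SE 0.09); adjusted over the list alone 2 rose and 4 fell. Camera called none of the 3 lists (adjusted p = 0.307, 0.334 and 0.817). The UQCRQ call was lost without any 1 of 7 arrays (adjusted p up to 0.0755), and that of ALDOC without wild-type sample 2 or SOD1(G93A) sample 3 (adjusted p up to 0.0546).

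Of 30 p53 targets and apoptosis genes, 1 rose and 3 fell (2 and 3 adjusted over the list alone). TP53I3 fell by 0.54 (SE 0.08), GADD45A by 0.44 (SE 0.10) and the death receptor TNFRSF10B by 0.35 (SE 0.08), and CASP9 rose by 0.44 (SE 0.09). Of 29 interferon and NF-kB genes 2 fell, CCL2 by 0.83 (SE 0.22) and OAS1 by 0.40 (SE 0.08), also adjusted over the list alone. Of 40 splicing factors, the neuronal RNA-binding genes ELAVL2 and CELF2 fell by 0.84 (SE 0.09) and 0.67 (SE 0.10) and MBNL2 rose by 0.60 (SE 0.07), with the same counts over the list alone. Camera called none of these lists (adjusted p = 0.857, 0.307 and 0.334). The CCL2 call was lost without any 1 of 9 arrays (adjusted p up to 0.0938), and that of TNFRSF10B without wild-type sample 11 (adjusted p = 0.0509). The calls of CASP9 and OAS1 were lost without samples 17 and 18 together, an omission added after the data were seen (adjusted p = 0.0677 and 0.0657). CELF2 ended below the lower quartile of the probe sets.

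Of 21 measured genes linked to ALS, 4 rose and 0 fell by limma (5 and 2 adjusted over the list alone, and 5 and 2 at an unadjusted p under 0.05). ERBB4, a neuregulin receptor, rose by 1.69 (SE 0.10), PRPH by 1.03 (SE 0.08), SPG11 by 0.30 (SE 0.06) and the motor protein gene KIF5A by 0.28 (SE 0.07). Camera called the list higher (adjusted p = 0.0422), but not with an estimated correlation (adjusted p = 0.977). Its call was also lost without wild-type sample 2, 8 or 14 or SOD1(G93A) sample 15 or 18 (adjusted p from 0.0522 to 0.0683), with the mean of a gene's probe sets (adjusted p = 0.0536) and among the probe sets brighter than the median one (adjusted p = 0.337). The SPG11 call was lost without samples 17 and 18 together, an omission added after the data were seen (adjusted p = 0.0871). The KIF5A call was lost without any 1 of 9 arrays (adjusted p up to 0.108), and a second KIF5A probe set was not called (0.42, SE 0.23, adjusted p = 0.380).

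**Figure D3:**
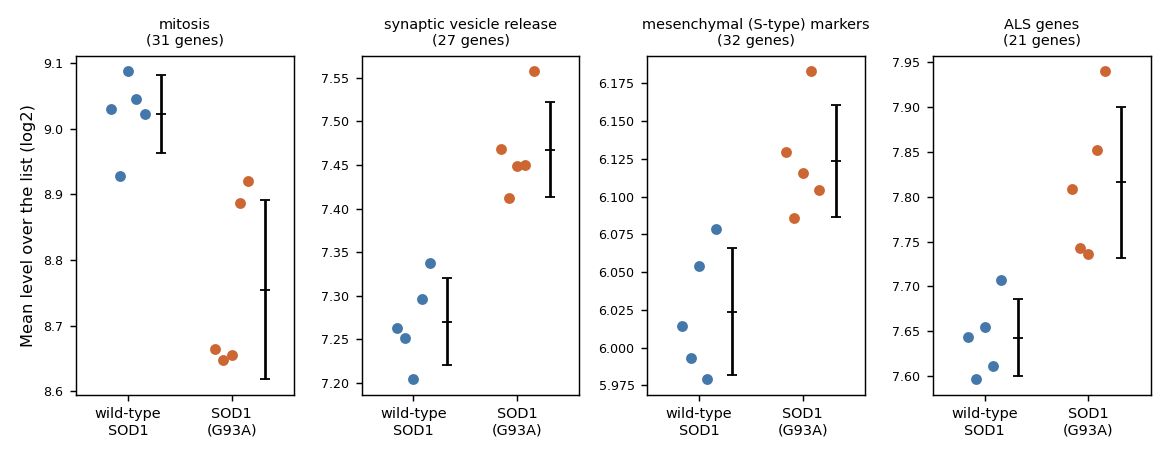
Mean level over the genes of each list (log2, vertical axes, which do not start at 0) in each array, 5 points per group, with the group mean and SD as a bar. Mitosis means fall from 9.02 to 8.76 and synaptic vesicle means rise from 7.27 to 7.47; the groups do not overlap in any of the 4 panels.

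Neighbouring genes moved together in 2 runs, 1 of them long. From SH3YL1 to ACYP2, neighbours on the short arm of chromosome 2, 180 of 201 named genes had a lower mean in the SOD1(G93A) line, 101 of them called, and 21 had a higher mean, 2 of them called. The median log2 fold change was −0.37, with quartiles of −0.52 and −0.15. The running median of 21 genes reached a size of 0.52, against a limit of 0.19 from 1000 shuffled gene orders (permutation p = 0.000999, the smallest that they can give). CENPA, RRM2, DPYSL5, PDIA6, TP53I3 and the neuroblastoma genes ALK (log2 fold change −0.44) and SOX11 (−0.53) lay in this stretch, as did MYCN, which was not lower (0.10, adjusted p = 0.753). The stretch held 12.7% of the named genes called lower. A second run, LINC00208 to INTS10, held 26 named genes, 18 with a higher and 8 with a lower mean (median log2 fold change 0.16); 9 were called higher and 0 lower. Without the genes from SH3YL1 to ACYP2, 1505 probe sets were called and the same 4 lists by camera, an alternative added after the data were seen.

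**Figure D4:**
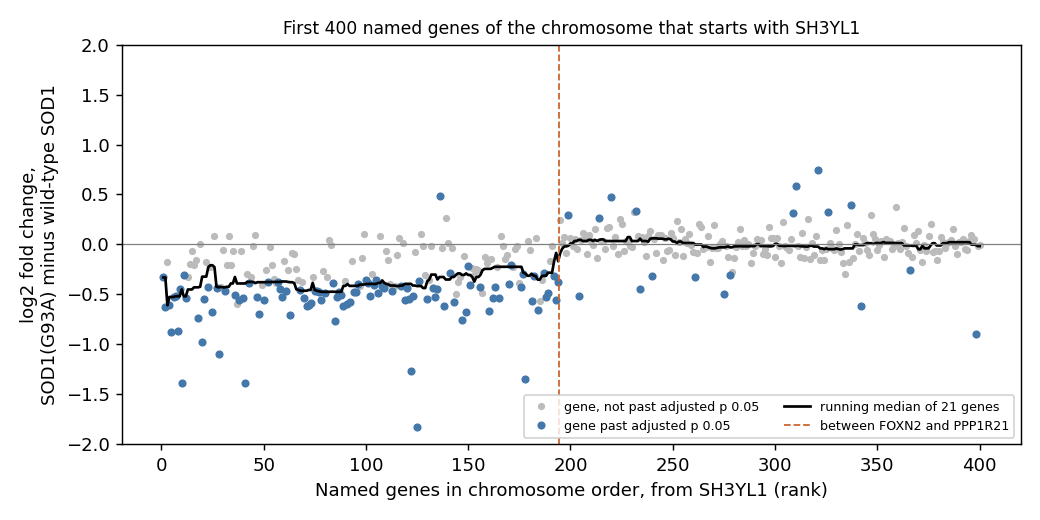
Log2 fold change (SOD1(G93A) minus wild-type SOD1, vertical axis) of the first 400 named genes of the chromosome, in gene order from SH3YL1, with called genes in blue and the running median of 21 genes as a line. The median over the 194 genes up to FOXN2 is −0.38, and over the 50 genes from PPP1R21 onwards it is 0.05. That boundary was chosen from these same values as the best single step.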

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

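In this part, both tests on the stretch of neighbouring genes were chosen only after that stretch was seen, as was the omission of its genes, and the other tests were set before their values were known.

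The first pattern is the number of genes that differed between the lines. Chance can be excluded: of 100 splits of the 10 arrays into 5 and 5, only 1, the real one, gave as many as 1643 probe sets or as many as 192 past the 2-fold threshold too, and the highest other counts were 1 and 1. For the 1643 calls, a technical shift of dim probes is argued against as their main source. Of them, 36.9% (95% interval 34.5 to 39.3) lay below the median level, where such a shift needs over 50%. That argument does not cover the 192 probe sets past 2-fold. Only 91 of them were also past both thresholds among probe sets brighter than the median one, tested alone. Runs of neighbouring genes that moved together held 8.21% (95% interval 6.80 to 9.79) of the called named genes, under the 20% set in advance for gains or losses of chromosome segments as a leading cause; whether these runs are gains or losses was not tested. What stays open is whether the SOD1(G93A) protein or another difference between the 2 transfected lines, such as drift or clonal origin, lies behind NNAT, HGF and the other genes, because construct and line cannot be separated in this design.

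The second pattern is the stretch of lower genes from SH3YL1 to ACYP2. Of its 131 genes brighter than the median probe set, 93.9% had a lower mean in the SOD1(G93A) line, with a median log2 fold change of −0.45, a share that decides nothing about the cause, because the stretch was picked for its lower genes. The best single step, chosen from these same values, lay between FOXN2 and PPP1R21, and the next 50 genes had a median of 0.05. Such a choice always places the boundary between neighbouring genes, so how sharply the shift ended was not tested. Array-to-array regional signal unrelated to the line is argued against by the arrays left out. Each array was left out in turn and the run found in the other 9. Of the left-out arrays, 10 of 10 lay nearer to their own group's mean over the run, relative to all named genes. With all arrays this mean was 0.77 ± 0.01 in wild-type and 0.43 ± 0.05 in SOD1(G93A) arrays (SD, n = 5). That gap adds no support, because the run was found in these same arrays. A candidate explanation, left open, is fewer copies of the end of the short arm of chromosome 2, a part that SH-SY5Y is known to carry in excess, in the SOD1(G93A) line; a loss from 3 to 2 copies would give −0.58 without compression, DNA was not analysed here, and lower transcription at an equal copy number was not tested.

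The third pattern is the lower level of mitosis genes, of which 30 of 31 had a lower mean in SOD1(G93A) arrays. The list's median of −0.26 lay below the middle 95% (−0.07 to 0.05) of 10000 random lists matched on mean level. Genes of like level thus did not fall as far. The comparison was planned to argue against signal compression of bright genes, but it decides nothing about it. Quantile normalization takes out a shift of all bright genes, so such random lists show no common fall whatever the cause. Random genes also lack the shared movement of mitosis genes, whose estimated correlation was 0.34. Array-to-array differences that the groups do not share are argued against by the exact permutation test of the array means (p = 0.00794), and without CENPA, which lies in the stretch above, that test gave p = 0.0159. Chance cannot be excluded for the camera result, as 14 of 100 splits gave as small a p as the real 5.04e-10. The smallest of the others, 2.49e-15, came from a split with 1 array of each group exchanged, which keeps most of the real contrast. A split with 2 arrays of each group exchanged gave 5.13e-13, so mitosis genes can also move together under groupings farther from the real one. SOD1(G93A) samples 3, 9 and 12 had means of 8.66, 8.65 and 8.66, and samples 15 and 18 had 8.89 and 8.92, near the lowest wild-type mean of 8.93 in sample 8; slower growth in the SOD1(G93A) line and culture density at harvest both stay open, as untested.

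For the lists as a whole chance cannot be excluded either: 25 of 100 splits gave as many as the 4 lists called by camera, and the highest other split gave 9.

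Single arrays stood apart from the rest of their group in 22 of 250 groups of 5 values tested, where chance gives 12.5. The measure is the gap to the nearest array as a share of the group's range. In the wild-type group, sample 2 stood apart for GLRX (0.772), ABCC1 (0.766), CHRNA3 (0.765), MS4A1 (0.821) and KIF5A (0.735). Sample 17 did so for MAGEA10 (0.762), HSPA2 (0.741), BAG3 (0.755), NRP2 (0.762) and for the means of the NRF2 targets (0.746) and of the glutamate receptor and calcium genes (0.798). Sample 14 did so for HGF (0.782) and TP53I3 (0.914), and sample 8 for ELAVL2 (0.731). The largest share was that of TP53I3, at 9.92 in sample 14 against 10.13 in the nearest array. In the SOD1(G93A) group, sample 18 stood apart for NNAT (0.755), EDIL3 (0.747) and STARD4 (0.792), and sample 9 for CCDC80 (0.790) and MVK (0.718). Sample 12 did so for BCHE (0.737) and for the mean of the proteasome genes (0.817), at 9.25 against 9.39 in the nearest array. Sample 15 did so for PPP2R2C (0.765).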

How the results depend on the processing

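The omissions of samples 17 and 18 together and of the stretch from SH3YL1 to ACYP2, and Fisher's test of the lists, were chosen after seeing the data. The count of called probe sets ran from 1213, with adjacent sample numbers as a block, to 1754, with quantile normalization, over all alternatives run, and from 1274 to 1562 with single arrays left out. The count past 2-fold ran from 180 to 193 with single arrays left out and fell to 92 among probe sets brighter than the median one, where fewer were tested. SOD1 missed the threshold in the 16 alternatives run for it, at −0.18 to −0.27. The 4 lists called by camera became 2 among brighter probe sets (synaptic vesicle release and mitosis) and 0 with an estimated correlation. With single arrays left out there were 3 or 4. Fisher's exact test of called members, which asks another question and treats genes as independent, called 7 lists and shared 2 of the 4. The 7 were axon guidance, matrix, glutamate receptors and calcium, noradrenergic identity, synaptic vesicle release, neuronal cytoskeleton and mitosis. No named gene past the threshold changed direction in any alternative run. Of 950 values of the 95 called named genes with 1 array left out, 112 in 18 genes were no longer past the threshold, mostly genes with small changes such as FTL and KIF5A; the cause was not tested beyond the smaller number of arrays. With the block 13 of the named genes lost their call, among them FTL, CCN1 and SPG11, with array weights 2, and with samples 17 and 18 out 16. Signal over background is not known, so where a value lies below the lower quartile, such as HGF in wild-type arrays, the size of the fold is uncertain.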

Other observations

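All 6 lists used here were written after the largest changes had been seen. Camera was run on them only at the preset correlation of 0.01, not with an estimated one. The tests of 5 of them were set before the lists' values were known, and that of the channels, without KCNA3 and KCNK1, was set after. Potassium, sodium and HCN channels changed more often than other named genes. Besides KCNA3 and KCNK1, 5 of 35 rose and 5 fell, or 28.6% against 9.60% (Fisher's exact test, 2-sided, p = 0.00125, adjusted p = 0.00753 over the 6 lists). KCNA3, a delayed rectifier of the Shaker family, fell by 1.84 (SE 0.11) to below the lower quartile of the probe sets, and the leak channel KCNK1 fell by 1.34 (SE 0.11). Of the others, KCNH2, the ERG channel, fell by 0.75 (SE 0.05) and the M-current subunit KCNQ3 by 0.58 (SE 0.06). KCNH6 and KCNH8 rose by 0.46 (SE 0.08) and 0.37 (SE 0.05), and the sodium channel SCN2A by 0.38 (SE 0.06). The list did not move one way (camera, adjusted p = 0.621), and KCNK3, which fell by 0.38, lay in the stretch of lower genes on chromosome 2.

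Besides NNAT, 5 of 27 other imprinted genes fell and 0 rose by limma. PEG10 fell by 1.24 (SE 0.07) and SGCE, its neighbour, by 0.79 (SE 0.08), and NAP1L5 fell by 0.78 (SE 0.07), DLX5 by 0.69 (SE 0.15) and INPP5F by 0.42 (SE 0.09). The hypothesis that imprinted genes change more often than others was not borne out and is not excluded (Fisher's exact test, 2-sided, p = 0.176), since a list of 27 is small and a p that misses the threshold does not show equal rates. Camera, which takes the direction into account, gave an adjusted p of 0.0505 over the 6 lists for a lower level.

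Other hypotheses taken from the largest changes stayed undecided for the same reason. CRABP2 and RARB rose by 2.25 and 1.44, but the other 27 measured retinoic acid targets were not called by camera (adjusted p = 0.621 over the 6 lists, 0.514 before adjustment): ALDH1A3 rose by 0.70 while RXRA, STRA6 and MEIS1 fell by 0.80, 0.49 and 0.32. MAGEA10 was alone among the cancer-testis genes measured, with 0 of 19 others called by limma (Fisher's exact test, 2-sided, p = 0.249). Beside HOXC10, 1 of 21 other HOX genes rose, HOXD10 by 0.56, and 2 fell, HOXC9 and HOXC11 by 0.48 each (Fisher's exact test, 2-sided, p = 0.447).

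A larger share of S-type or stromal cells may account for the higher S-type markers. The median log2 fold change of 13 abundant transcripts of such cells was 0.14 (0.01 to 0.28 at 2 standard errors), with 9 higher and 4 lower (camera, adjusted p = 0.0162), below the 0.47 of the 6 S-type markers that rose. The comparison was planned to argue against a larger share at such a value, but it decides nothing: FN1, CD44 and VIM belong to both sets, and the 6 markers were picked because they rose. SNAI2, which fell by 1.03, was the only S-type marker called lower, and the question stays open.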
